A study of Mus musculus with 20 samples.

How the data were processed

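RNA sequencing measured polyadenylated mRNA in whole kidneys of 20 male C57BL/6J mice of 18 to 22 g, with 5 animals in each of 4 groups. Per the labels' protocols, RNA with an integrity number of at least 7 was made into libraries of 300 to 350 bp fragments and sequenced as paired 150 bp reads on an Illumina NovaSeq. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, StringTie and DESeq2 without versions, and the mouse genome build mm10 (GRCm38). The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Genes on opposite strands that overlap therefore cannot be told apart, and genes with near-identical copies may share reads.

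Per the file headers, the authors deposited 1 table with a raw read count per gene and library and with their own group comparisons. The values taken as counts are whole numbers whose totals differ between libraries. The fold changes in the authors' deposited table are on the log2 scale, per the size given in the series' design text. The p-value and q-value columns of the authors' deposited table belong to the same comparisons. They were used only to count genes at q < 0.05 and a change of more than 2-fold. Groups were taken from the sample titles, and all 20 count columns matched 1 library each. Replicate numbers in the text are those of the titles.

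The table holds 25638 genes, of which 25274 (98.6%) matched GENCODE vM21 by symbol and place, and 95.7% of these had both ends within 1000 bp. Coordinates are those of the deposited table, in GRCm38. Totals per library were 25085860 to 34003338 counts in control, 10714532 to 44910747 in cisplatin, 27398523 to 41638560 at 15 mg/kg and 25972128 to 49602115 at 30 mg/kg. Between replicates of a group, chi-square per degree of freedom was 28.45 to 1926.32 over 40 pairs, so no pair was a repeat of 1 library. Levels of 3 counts cover counting error only, and reads without molecular identifiers are not independent molecules.

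Genes were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F-test on counts as deposited, after TMM scaling and filterByExpr by group, which left 14858 genes. All 20 libraries entered 1 fit with 16 residual degrees of freedom, and the common biological coefficient of variation was 0.374. Adjusted p values in the text are from this test with Benjamini-Hochberg adjustment over the tested genes, unless camera, DESeq2 or a permutation test is named, and ± after a log2 fold change is its standard error. The comparisons were cisplatin with control, each dose with cisplatin, each dose with control, the doses with each other and the mean of both doses with cisplatin. CPM were computed on TMM-scaled library sizes, with factors from 0.382 to 1.4, so that they need not sum to the same total in each library, and ± after a CPM is the SD of 5 animals.

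A total of 43 gene lists and a rule for the genes named were fixed before the data were examined, and 40 lists had at least 5 tested genes. Lists and KEGG pathways of 10 to 500 tested genes (270 pathways, 5250 genes, annotation as in the deposited table) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjustment was within a comparison. Each test was repeated with an estimated correlation, which ended every list call, and with fry, which asks whether a list's genes move one way on balance. List means per animal were compared by 2-sided exact permutation tests over all 252 splits of 5 against 5. The 3003 splits of 10 against 5 were also enumerated in full, in place of the random permutations first planned. Correlations across the 10 animals given 7-HCG used 100000 permutations. They were repeated without 2 animals over all 40320 orderings, and around the dose means over all 14400 orderings within doses.

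Some genes that the rule named are not reported here. The rule named a fixed panel of 14 genes, the 10 largest rises and 10 largest falls among called genes with separate groups and a mean of at least 2 CPM, without model names, and up to 4 members of each list with the smallest p. From these the genes in the text were selected after their values were seen, and calls that held under the alternatives were favoured. Of 662 called entries that the rule named in 5 comparisons, 272 (41.1%) held their call and stayed within 1.5-fold of their log2 fold change in all alternatives other than the replicate block. Among entries in the text the share was 79 of 116 (68.1%), and among the others 193 of 546 (35.3%). For cisplatin with control it was 20 of 37 (54.1%) in the text and 3 of 88 (3.4%) outside it.

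Comparisons that share libraries were set beside simulated groups, once with no group differing and once with the cisplatin effect kept and no 7-HCG effect (10 draws each), and beside splits of the cisplatin libraries into separate parts. The stability of the opposite-sign share was judged against a 95% binomial interval over genes, which are not independent. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, 1 to 6 of 14658 unchanged genes were called per comparison.

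The alternatives were DESeq2 size factors, library totals as the only scaling, no low-count filter, a filter at 1 CPM in 5 libraries, DESeq2 1.42.0, limma voom with sample weights, a fit of the compared groups only, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the fits without cisplatin replicates 9 and 10, without mitochondrial mRNAs, without both, without control replicates 2 and 5, and with an adjustment for GC content and exon length. The tests of the mitochondrial mRNA share and the relations across animals were also added after the data were seen. Counts of alternatives given for single genes and lists leave out the replicate block, and the totals over all of them include it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.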

Results

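The series measured polyadenylated mRNA in whole kidneys of 20 male C57BL/6J mice, a standard inbred laboratory strain. Cisplatin is a platinum chemotherapy drug that injures the proximal tubule, the nephron segment that takes up most of the filtered solutes. The compound tested was 7-hydroxycoumarin-β-D-glucuronide (7-HCG), a coumarin conjugated to glucuronic acid. The mice fell into 4 groups of 5. Control mice received vehicle and saline, and cisplatin mice received vehicle and a single intraperitoneal dose of 10 mg/kg cisplatin. The other 10 mice received 7-HCG by mouth at 15 or 30 mg/kg daily for 5 days with the same cisplatin dose on day 3. Kidneys were taken 72 h after cisplatin. No group received 7-HCG without cisplatin, so each 7-HCG comparison with control combines both treatments. The libraries held 10714532 to 49602115 counts, of which 3 counts in a library correspond to 0.06 to 0.28 CPM, counts scaled to library size. The 2-sided comparisons below test 14858 genes in 1 edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment, at an adjusted p below 0.05.

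The libraries differed in how much of their count came from the 13 mRNAs encoded by the mitochondrial genome. These mRNAs took 33.0% ± 7.75 of the counts in control (SD, n = 5), 42.8% ± 29.0 in cisplatin, 5.33% ± 1.56 at 15 mg/kg 7-HCG and 6.81% ± 1.12 at 30 mg/kg. Within the cisplatin group, replicates 9 and 10 stood at 77.7% and 70.6%, while the other 3 libraries ranged from 16.6% to 27.3%. The share was lower at both doses than in cisplatin and than in control (exact permutation test, p = 0.00794, the smallest that 252 splits allow, adjusted p = 0.0111 over 7 comparisons). The difference in mean share between cisplatin and control did not pass (exact permutation test, p = 0.452), nor did that between the 2 doses (exact permutation test, p = 0.119). Cisplatin libraries lay both below and above the control range of 24.6% to 45.5%. The lower share separated the 7-HCG libraries from all others. With these mRNAs left out before scaling, 5629 and 4141 genes were called at 15 and 30 mg/kg against cisplatin, compared with 5578 and 4148 with them.

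**Figure D1:**
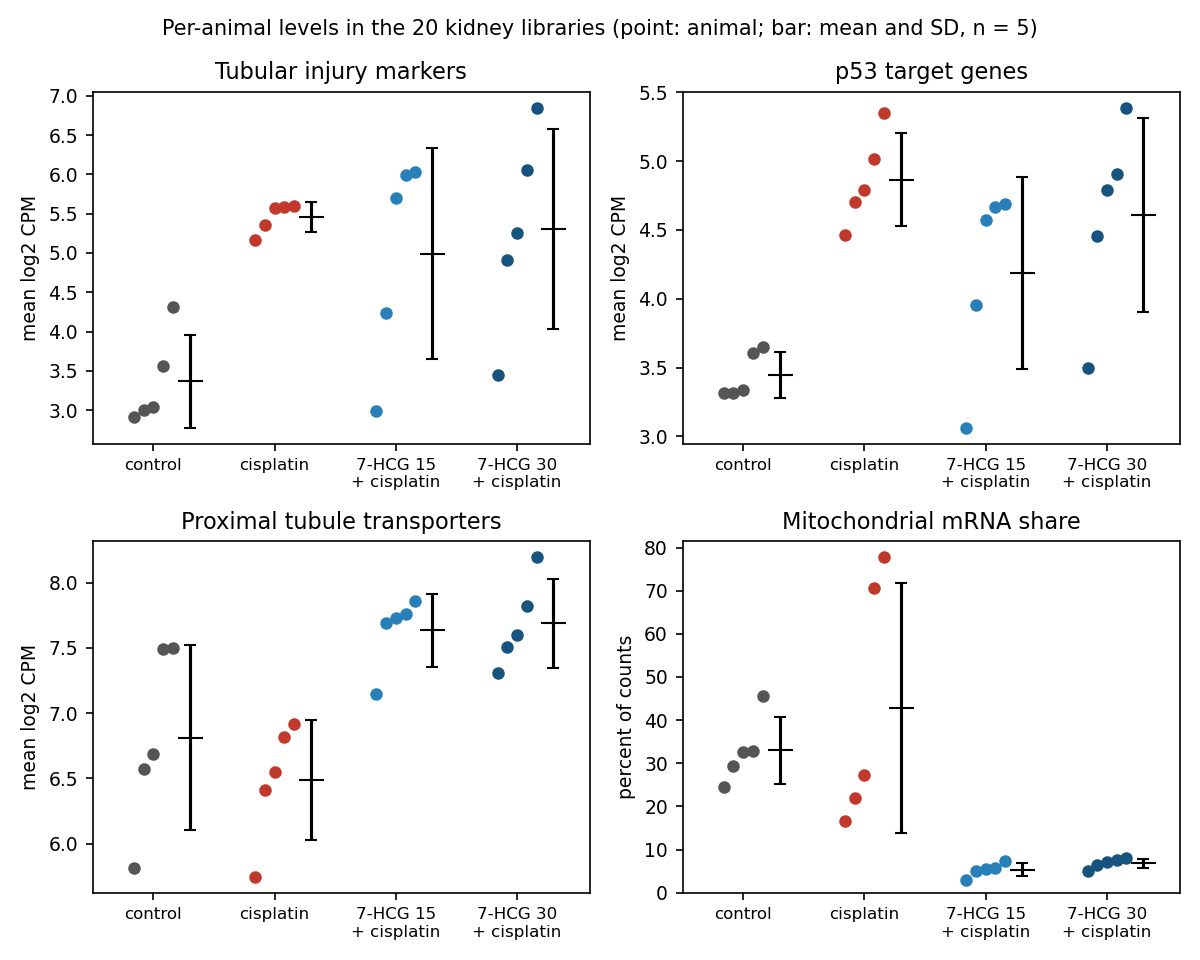
Per-animal levels in the 4 groups. Each point is 1 kidney library (n = 5 per group, ordered by value for display), and the black bar gives the mean and SD. The y axes give the mean log2 CPM of the gene list named in the title or, at the lower right, the percent of counts from mitochondrial mRNAs. The 7-HCG animals spread from 2.98 to 6.84 in the injury markers, while all 10 lie below 9% in the mitochondrial share.

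The comparison of cisplatin with control asked which genes the drug changed in the kidney. Of all 14858 tested genes 13.4% were called (1250 up, 744 down), and counts of list members are to be read beside this share. The mean level of tubular injury markers was higher in each cisplatin animal than in any control. The mean log2 CPM of the injury list was 3.37 ± 0.59 in control and 5.45 ± 0.19 in cisplatin (SD, n = 5), a difference of 2.09 (exact permutation test, p = 0.00794, adjusted p = 0.0397 over 5 comparisons). It did not pass with library totals as the only scaling (1.56, exact permutation test, adjusted p = 0.198). Without cisplatin replicates 9 and 10 it was 2.11 with the groups still separate, where 3 against 5 animals cannot give a smaller p (exact permutation test, adjusted p = 0.0893). Of its 29 tested genes 13 rose and 1 fell, and 16 rose and 1 fell when adjusted over the list alone. Lcn2, which encodes the urinary injury marker NGAL (chromosome 2, 32384633 to 32388252, GRCm38), rose 20-fold, from 18.2 ± 16.1 to 364 ± 94.2 CPM (log2 fold change 4.32 ± 1.04 SE, adjusted p = 0.0136). Saa3, an acute phase gene of a family of close copies, rose by 4.81 ± 1.05, from 0.044 ± 0.0697 CPM in control, where 3 of 5 libraries held no count, to 1.43 ± 0.543 CPM. The fibrinogen chain genes Fgg and Fga rose by 6.76 ± 1.08 and 4.08 ± 0.70 on the log2 scale. Sox9, a transcription factor of regenerating tubule cells, rose by 5.30 ± 1.07. Without control replicates 2 and 5 the calls of Lcn2 (5.51, adjusted p = 0.0515) and Sox9 (5.66, adjusted p = 0.0574) ended. Havcr1, which encodes the tubular injury marker KIM-1 (chromosome 11, 46735080 to 46779578), was higher by 3.58 ± 1.02 (adjusted p = 0.0279). Its call ended in 7 of 22 alternatives. These were the fits without control replicate 1 (adjusted p = 0.0534), 5 (0.0724), 7 (0.0545) or 2 and 5 together (0.122), without cisplatin replicate 6 (0.056), with library totals alone (0.0861) and without a low-count filter (0.0513). Krt20 was higher by 3.77 ± 1.56 without passing the test (adjusted p = 0.118). Its value ranged from 3.46 to 7.31 over the alternatives, and 1 of 22, DESeq2, called it (3.74, adjusted p = 0.0382). The injury list was called by camera, a competitive gene set test (adjusted p = 6.47e-07), but not with an estimated correlation between its genes (adjusted p = 0.437).

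Targets of p53, the transcription factor activated by DNA damage, were higher after cisplatin. Of 32 tested targets 20 rose and none fell (24 adjusted over the list alone), with camera adjusted p = 8.8e-12 and adjusted p = 0.324 with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), rose 17.2-fold, from 11.5 ± 6.19 to 198 ± 55.3 CPM (log2 4.11 ± 0.78, adjusted p = 0.00443). Sesn2, Ccng1 and Psrc1 rose by 1.73 ± 0.27, 1.69 ± 0.33 and 4.18 ± 0.69. Plk3 rose by 5.12 ± 0.90, and by 3.03 without cisplatin replicates 9 and 10. Of 28 pro-apoptotic genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.00208 and adjusted p = 0.324 with an estimated correlation. Bax, a pro-apoptotic effector and p53 target, rose by 1.05 ± 0.24 (adjusted p = 0.0098), a call that ended with library totals as the only scaling (0.75, adjusted p = 0.209) and without control replicates 2 and 5 (0.90, adjusted p = 0.0869). The survival gene Bcl2 (-0.39 ± 0.24, adjusted p = 0.287) was not called.

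The p38 MAPK pathway, which the study's title names, was examined as a list of 36 tested genes, of which 12 rose and 1 fell (13 and 2 adjusted over the list alone). Camera gave adjusted p = 0.000123, and adjusted p = 0.306 with an estimated correlation. Mapk14, which encodes p38α (chromosome 17, 28691342 to 28748404), was not called (0.30 ± 0.22, adjusted p = 0.396), with 73.7 ± 35 CPM in cisplatin and 59.8 ± 8.57 in control. Its difference changed sign without cisplatin replicate 10 (-0.05). Mapk11, for p38β, was not called either (0.42 ± 0.32, adjusted p = 0.403). Mapk13, for p38δ, rose 4.48-fold (log2 2.16 ± 0.39, adjusted p = 0.00327), and the upstream kinase gene Map3k6 rose 17.1-fold (4.09 ± 0.70). These rises were 1.43 and 2.68 without cisplatin replicates 9 and 10. Map2k3, for a kinase that phosphorylates p38, passed narrowly (0.96 ± 0.32, adjusted p = 0.0484). It lost its call in 17 of 22 alternatives, and its value was 0.37 without cisplatin replicate 10. Immediate early genes, which respond within minutes to stress signals, rose in 15 of 22 cases and fell in none (16 adjusted over the list alone), with camera adjusted p = 1.47e-07 and adjusted p = 0.324 with an estimated correlation. Atf3 and Junb rose by 3.24 ± 0.69 and 2.86 ± 0.63. Both calls ended without cisplatin replicates 9 and 10 (2.04, adjusted p = 0.0572, and 1.57, adjusted p = 0.0952). RNA abundance was measured here, not kinase phosphorylation.

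Glucocorticoid-responsive genes rose in 11 of 14 cases (12 adjusted over the list alone), among them Fkbp5 (2.75 ± 0.41) and the clock gene Per1 (2.24 ± 0.38, and 1.40 without cisplatin replicates 9 and 10). The metallothionein genes Mt1 and Mt2, members of a family of close copies whose counts may be shared, rose by 3.72 ± 0.63 and 5.23 ± 0.84. Of 36 genes for fatty acid oxidation and other PPARα targets 10 rose and none fell (11 adjusted over the list alone), with Angptl4 at 3.23 ± 0.53. Of 29 targets of the oxidative stress regulator NRF2, 10 rose and 1 fell (10 and 2 adjusted over the list alone). Srxn1, for sulfiredoxin, rose by 1.96 ± 0.50, and Me1, for malic enzyme, fell by 1.01 on the log2 scale (SE 0.21). The call of Srxn1 ended without control replicates 2 and 5 (1.78, adjusted p = 0.122), and that of Me1 with library totals alone (-1.27, adjusted p = 0.0526). Camera adjusted p was 2.48e-09 for the glucocorticoid list, 3.11e-06 for fatty acid oxidation and 0.00205 for NRF2. With an estimated correlation the adjusted p values were 0.181, 0.437 and 0.529. Cyp27b1, for the enzyme that activates vitamin D, rose by 5.77 ± 1.04, and by 2.98 without cisplatin replicates 9 and 10.

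Lower after cisplatin were genes of dividing cells and markers of several cell types other than the tubule, but not of neutrophils (3 of 6 rose and none fell under both adjustments, camera adjusted p = 0.231). The neutrophil list mean was high only in cisplatin replicates 9 (1.373) and 10 (1.555). It lay between -1.524 and -0.99 in the other cisplatin libraries and between -1.151 and -0.803 in control. Of 34 cell cycle genes 9 fell and none rose (18 adjusted over the list alone). Mki67 fell by 2.11 (SE 0.50) and Mcm6 by 1.16 (SE 0.27) on the log2 scale, and without cisplatin replicates 9 and 10 they stood at -2.09 (adjusted p = 0.0581) and -1.06 (adjusted p = 0.0625) and were not called. Of 30 extracellular matrix genes 9 fell and none rose, the same counts as when adjusted over the list alone, with Vim at -1.68 ± 0.28. The falls were not shared by cisplatin replicate 9, whose matrix mean of 6.272 lay above all controls (4.803 to 6.002). The other cisplatin libraries stood at 3.336 to 3.9. Control replicates 2 and 5, in which adipose tissue markers were high, had the highest control means of the matrix, fibroblast and endothelial lists. Of 11 podocyte markers, which label the filtration barrier, 7 fell and 1 rose under both adjustments. Of 12 fibroblast and mural cell markers 5 fell and none rose (6 adjusted over the list alone), with Acta2 at -2.15 ± 0.36 and Tagln at -1.99 ± 0.34. Here too cisplatin replicate 9 (list mean 6.15) lay within the controls (5.549 to 6.652). Of 10 T and NK cell markers 6 fell and none rose (9 adjusted over the list alone), and of 7 red blood cell markers 5 fell and none rose (6 adjusted over the list alone). Thy1 was at 7.35 ± 3.85 CPM in control and 0.319 ± 0.192 in cisplatin (log2 -4.31 ± 0.47), and Hba-a2, a globin gene with a near-identical copy, at 20.5 ± 11.2 and 0.403 ± 0.45 (-5.78 ± 1.11). At low counts in cisplatin were also Cxcl9 (0.105 ± 0.131 CPM against 7.61 ± 2.95, log2 -6.03 ± 1.01), Aplnr (0.192 ± 0.125 against 7.34 ± 7.2, -5.19 ± 0.95) and Alas2 (0.101 ± 0.163 against 4.71 ± 2.88, -5.70 ± 0.88), whose fitted changes depend on the prior count. Camera adjusted p ranged from 1.62e-07 for the cell cycle and T and NK cell lists to 0.000158 for fibroblast and mural cells. An estimated correlation gave adjusted p of 0.299 for cell cycle, 0.437 for matrix, 0.431 for podocytes, 0.365 for fibroblasts, 0.15 for T and NK cells and 0.15 for red blood cells. Of 12 endothelial markers 4 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00373, and adjusted p = 0.489 with an estimated correlation). Their mean in cisplatin replicate 9 (5.978) also lay within the controls (5.466 to 6.547). Of 15 macrophage and monocyte markers 3 fell and none rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.00514, and adjusted p = 0.437 with an estimated correlation). Of 9 adipose tissue markers, which were high in control replicates 2 and 5, 6 fell and none rose (7 adjusted over the list alone, camera adjusted p = 0.113). The adipose list mean was 4.953 and 7.26 in these 2 controls. It was also high in replicate 5 at 15 mg/kg (4.219) and replicate 6 at 30 mg/kg (4.413), and lay between -0.807 and 2.342 in all other libraries. The 2 7-HCG libraries were left out only 1 at a time. Camera called the adipose list lower without control replicate 7 (adjusted p = 0.0096) or 8 (0.0179).

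As a list, proximal tubule transporters were not called after cisplatin. Of 39 tested, 3 rose and 5 fell under both adjustments (camera adjusted p = 0.231), and the per-animal list mean differed by -0.32 (exact permutation test, p = 0.452). Camera called the list lower without control replicate 5 (adjusted p = 0.00292) and without control replicates 2 and 5 (adjusted p = 2.4e-05). The sulfate transporter gene Slc13a1 rose by 1.76 ± 0.33. The phosphate transporter gene Slc34a1 (-0.54 ± 0.44) and the organic anion transporter gene Slc22a6 (-0.30 ± 0.30) were not called, though Slc34a1 was with limma voom (-1.02, adjusted p = 0.0342). Of 10 markers of the S3 segment, the straight part of the proximal tubule, 4 fell and none rose (5 adjusted over the list alone), with camera adjusted p = 0.00208 and adjusted p = 0.437 with an estimated correlation. Slco1a1 fell by 2.21 (SE 0.54), a call that ended without cisplatin replicates 9 and 10 (-1.98, adjusted p = 0.091), as did that of the list (adjusted p = 0.113). Of 10 androgen-dependent kidney genes 6 fell and none rose (8 adjusted over the list alone), with camera adjusted p = 0.00364 and adjusted p = 0.437 with an estimated correlation.

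In all, cisplatin raised 1250 and lowered 744 genes, of which 749 rose and 630 fell by more than 2-fold. In the authors' deposited table, 796 genes were higher and 1050 lower in cisplatin at q < 0.05 and the same size. The count of 1994 rested on few libraries. It was 829 without cisplatin replicate 10, 979 without control replicate 2 and 1124 without control replicate 5. It was 691 without cisplatin replicates 9 and 10 together. Without control replicates 2 and 5, in which adipose tissue markers were high, it was 292. Under library totals alone it was 883, with 207 genes up and 676 down. In simulated data with 100 genes changed by each size, the test recovered 31% of genes changed 2-fold and 79% of those changed 4-fold in this comparison. Far fewer genes changed there than were called here, which makes the Benjamini-Hochberg cut stricter, so these rates do not carry over to the data. Of 270 annotated KEGG pathways, camera called 3: adipocytokine signaling was higher (adjusted p = 0.0349), and cell adhesion molecules (adjusted p = 0.0021) and the malaria pathway (adjusted p = 0.0349) were lower. Each had adjusted p = 0.958 with an estimated correlation. The count of pathways ranged from 1 to 25 with 1 library left out, and was 30 without cisplatin replicates 9 and 10.

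**Figure D2:**
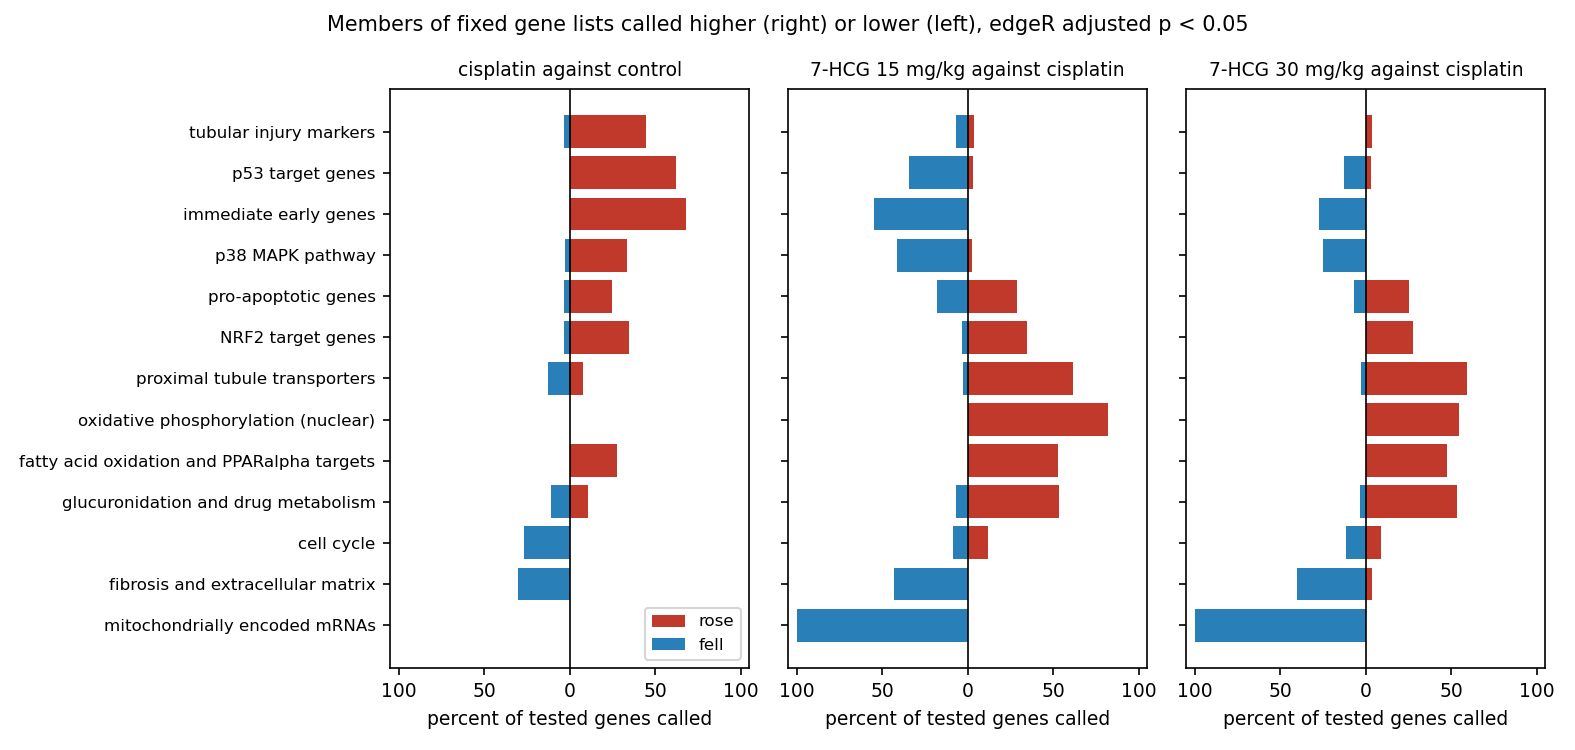
Share of each fixed gene list that passed the test in 3 comparisons. The x axis gives the percent of the tested genes of a list called higher (red, to the right) or lower (blue, to the left), and the y axis the list. Injury and p53 lists rise after cisplatin, while transporters, oxidative phosphorylation and fatty acid oxidation are higher and mitochondrial mRNAs lower at both 7-HCG doses than in cisplatin.

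The comparisons of each 7-HCG dose with cisplatin asked what the compound changed in cisplatin-treated kidneys. Of all 14858 tested genes 37.5% were called at 15 mg/kg (2811 up, 2767 down) and 27.9% at 30 mg/kg (2180 up, 1968 down). Counts of list members are to be read beside these shares, since any list would hold many called genes. Proximal tubule transporters were higher at both doses. Their mean log2 CPM was 6.49 ± 0.46 in cisplatin, 7.64 ± 0.28 at 15 mg/kg and 7.69 ± 0.34 at 30 mg/kg (SD, n = 5). The differences of 1.15 and 1.20 passed the exact permutation test (p = 0.00794 and adjusted p = 0.0132 for each), and all 10 animals lay above all 5 cisplatin animals. At 15 mg/kg 24 of 39 transporters rose and 1 fell, the same when adjusted over the list alone. At 30 mg/kg 23 rose and 1 fell (25 and 1 adjusted over the list alone). Slc22a6, for the renal organic anion transporter OAT1 (chromosome 19, 8617996 to 8628299), was at 324 ± 77.7 CPM in cisplatin, 816 ± 131 at 15 mg/kg (log2 1.33 ± 0.30, adjusted p = 0.00235) and 794 ± 116 at 30 mg/kg (1.29 ± 0.30, adjusted p = 0.00461). Slc17a3, for a urate transporter, rose by 1.42 ± 0.29 and 1.49 ± 0.29, and Slc3a1, for a cystine transporter subunit, by 2.30 ± 0.40 and 2.44 ± 0.40. The exception was the sodium-proton exchanger gene Slc9a3, which fell by 1.75 (SE 0.32) and 1.56 (SE 0.31), the latter not with library totals alone (-1.12, adjusted p = 0.0514). Slc34a1 rose by 1.19 ± 0.45 (adjusted p = 0.0394) and 1.33 ± 0.45 (adjusted p = 0.031). Its call at 15 mg/kg ended when cisplatin replicate 2 (adjusted p = 0.0974), 3 (0.0697), 6 (0.0643) or 9 (0.0935) or dose-group replicate 1 (0.0663), 3 (0.0867), 5 (0.0725) or 7 (0.0563) was left out. At 30 mg/kg it ended without cisplatin replicate 2 (0.0791), 3 (0.0524), 6 (0.0505) or 9 (0.078) or dose-group replicate 1 (0.90, adjusted p = 0.131), and in a fit of the compared groups only (adjusted p = 0.0535). Of 12 markers of the S1 and S2 segments 7 rose at 15 mg/kg and 9 at 30 mg/kg, and none fell (9 and 10 adjusted over the list alone), with the endocytic receptor gene Lrp2 at 1.56 ± 0.35 and 1.55 ± 0.35 and Miox at 2.05 ± 0.38 and 1.77 ± 0.38. Camera adjusted p for transporters was 4.97e-07 and 1.97e-08, and for S1 and S2 markers 0.000445 and 4.7e-05. For both lists, adjusted p with an estimated correlation was 0.672 at 15 mg/kg and 0.538 at 30 mg/kg.

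Nuclear genes of mitochondrial energy metabolism were higher as well. Of 33 nuclear oxidative phosphorylation genes 27 rose at 15 mg/kg and 18 at 30 mg/kg, and none fell (31 and 24 adjusted over the list alone). Sdha, for a subunit of succinate dehydrogenase, rose by 1.16 ± 0.17 and 1.23 ± 0.17, and Atp5b, for a subunit of ATP synthase, from 977 ± 180 CPM to 2900 ± 348 and 2550 ± 575 (1.57 ± 0.22 and 1.38 ± 0.22). Sdhd rose by 1.41 ± 0.20 and 1.43 ± 0.20, with 0.88 at 15 mg/kg after adjustment for GC content and exon length. Of 36 fatty acid oxidation genes 19 and 17 rose and none fell (19 and 18 adjusted over the list alone), with Hadha at 1.44 ± 0.20 and 1.19 ± 0.20 and Hadh at 1.39 ± 0.21 at each dose. Camera adjusted p was 4.44e-12 and 3.62e-09 for oxidative phosphorylation and 4.67e-05 and 7.22e-07 for fatty acid oxidation. With an estimated correlation adjusted p was 0.672 and 0.538 for both lists. In contrast, all 13 mitochondrially encoded mRNAs were lower at both doses (camera adjusted p = 4.95e-08 and 2.38e-09, and adjusted p = 0.672 and 0.538 with an estimated correlation). For mt-Nd5 the log2 fold changes were -4.31 ± 0.62 and -4.01 ± 0.61, and -2.28 and -2.02 without cisplatin replicates 9 and 10. For mt-Co1 they were -4.23 ± 0.68 and -3.83 ± 0.66, and -1.93 and -1.58 without these 2 libraries.

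Genes of glucuronidation and drug metabolism rose in 15 of 28 cases at each dose, with 2 and 1 falling (16 up and 3 down, and 17 up and 1 down, adjusted over the list alone). Cyp4b1 rose by 2.53 ± 0.48 and 2.93 ± 0.49. Ugt2b38 and Cyp2d26, members of families of close copies whose counts may be shared, rose by 2.60 ± 0.61 and 2.73 ± 0.62 and by 2.13 ± 0.36 and 1.86 ± 0.35. Of 10 androgen-dependent kidney genes 8 rose at each dose and none fell (8 and 10 adjusted over the list alone). Camera adjusted p was 0.00049 and 2.59e-05 for drug metabolism and 0.00108 and 2.79e-05 for the androgen-dependent list. With an estimated correlation adjusted p was 0.672 and 0.538 for both. Of 29 NRF2 targets 10 and 8 rose and 1 and 0 fell under both adjustments, including Me1 (1.19 ± 0.21 and 1.37 ± 0.21) and Gsta3 (1.83 ± 0.32 and 1.57 ± 0.32), a member of a family of close copies. Camera adjusted p for NRF2 was 0.0145 and 0.0135, and with an estimated correlation adjusted p was 0.78 and 0.809. Without cisplatin replicates 9 and 10 the calls of this list ended (adjusted p = 0.143 and 0.126). They also ended after adjustment for GC content and exon length (0.0806 and 0.0707). At 15 mg/kg its call also ended without dose-group replicate 2 (adjusted p = 0.0585), and at 30 mg/kg without cisplatin replicate 9 (0.078) or dose-group replicate 6 (0.0992). Of 27 interferon-stimulated genes 8 rose and none fell at 15 mg/kg under both adjustments (camera adjusted p = 0.00594, and adjusted p = 0.78 with an estimated correlation). This call ended without cisplatin replicates 9 and 10 (adjusted p = 0.187) and without replicate 10 alone (0.054). Among the genes with the largest rises, the lipoprotein gene Apom rose by 3.64 ± 0.36 and 3.24 ± 0.35 and the pyrimidine catabolism gene Dpys by 2.91 ± 0.47 and 2.55 ± 0.47. Fam151a rose by 4.58 ± 0.93 at 30 mg/kg.

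No difference in the list mean of the injury markers between 7-HCG and cisplatin passed the test, with a wide spread among the 7-HCG animals. Their mean log2 CPM was 4.99 ± 1.34 at 15 mg/kg and 5.30 ± 1.28 at 30 mg/kg against 5.45 ± 0.19 in cisplatin (SD, n = 5). The differences of -0.46 and -0.15 did not pass the exact permutation test (p = 0.5 and 0.817, adjusted p = 0.817 for each). They were 0.04 without replicate 3 of the 15 mg/kg group and 0.31 without replicate 1 of the 30 mg/kg group. Of 29 injury markers 1 rose and 2 fell at 15 mg/kg, and 1 rose and none fell at 30 mg/kg (none at either dose adjusted over the list alone). Lcn2 stood at 320 ± 309 and 314 ± 321 CPM against 364 ± 94.2 in cisplatin (-0.19 ± 0.91, adjusted p = 0.886, and -0.21 ± 0.91, adjusted p = 0.882). Havcr1 was at 75.7 ± 54.2 and 98.5 ± 91.3 CPM against 32.7 ± 31.5 (1.19 ± 0.93, adjusted p = 0.322, and 1.57 ± 0.93, adjusted p = 0.214), and Cdkn1a at 162 ± 164 and 212 ± 166 against 198 ± 55.3 (-0.29 ± 0.69, adjusted p = 0.765, and 0.10 ± 0.69, adjusted p = 0.928). Of 32 p53 targets 1 rose and 11 fell at 15 mg/kg and 1 rose and 4 fell at 30 mg/kg under both adjustments. Camera called the list at 15 mg/kg only (adjusted p = 0.0192 and 0.327), and with an estimated correlation adjusted p was 0.838 and 0.883. The call at 15 mg/kg ended without cisplatin replicate 10 (adjusted p = 0.0646) and without dose-group replicate 1 (0.0502) or 3 (0.175). In the direct test between the doses no gene was called, while camera called the p53 list higher at 30 mg/kg (adjusted p = 0.00123, and 0.975 with an estimated correlation). Across the 10 animals given 7-HCG the injury mean ranged from 2.98 to 6.84. Replicates 1 (4.231) and 3 (2.985) at 15 mg/kg and 1 (3.453) at 30 mg/kg lay within the control range of 2.917 to 4.316. Replicate 8 at 30 mg/kg (4.912) was also below all cisplatin animals (5.16 to 5.601). Above all of these lay replicates 2, 5 and 7 at 15 mg/kg and 5 and 6 at 30 mg/kg.

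Across these 10 animals, 3 relations of the injury mean were tested. The injury mean rose with the p53 mean (Pearson r = 0.969, permutation p = 2e-05, adjusted p = 6e-05, Spearman rho = 0.927, permutation p = 0.00026). It also rose with the immediate early gene mean (r = 0.955, permutation p = 4e-05, rho = 0.939, permutation p = 3e-04). Leaving out the genes that lists share gave r = 0.959 and 0.947. The transporter mean was lower where injury was higher (r = -0.724, permutation p = 0.0175, rho = -0.745, permutation p = 0.0175). Without the 2 animals farthest from the median, replicate 3 at 15 mg/kg and replicate 1 at 30 mg/kg, r was 0.907, 0.904 and -0.534 (exact permutation test over 8 animals, p = 0.00434, 0.00496 and 0.177, adjusted p = 0.00992, 0.00992 and 0.177 over 4 relations, with 1 of an inflammatory list included), so the relation with transporters passed only with these animals, whose removal also narrows the range of injury. Around the means of the 2 doses, r over the 10 animals was 0.985, 0.977 and -0.746 (exact permutation test within doses, p = 6.94e-05, 0.000208 and 0.0209, adjusted p = 0.000278, 0.000417 and 0.0209).

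Among the 36 genes of the p38 MAPK pathway, 1 rose and 15 fell at 15 mg/kg and 9 fell at 30 mg/kg, the same counts as when adjusted over the list alone. Camera gave adjusted p = 0.00668 and 0.00387, and adjusted p = 0.672 and 0.538 with an estimated correlation. Both calls ended without cisplatin replicates 9 and 10 (adjusted p = 0.156 and 0.13), and that at 15 mg/kg also without replicate 10 alone (0.054). Mapk14 was not called at either dose (0.20 ± 0.22, adjusted p = 0.494, and 0.17 ± 0.22, adjusted p = 0.591). Without cisplatin replicate 10 it was higher at both (0.56, adjusted p = 0.0148, and 0.52, adjusted p = 0.03). Mapk11 fell by 0.89 (SE 0.32, adjusted p = 0.0334) and 1.33 (SE 0.32, adjusted p = 0.00577). With library totals as the only scaling neither fall passed (adjusted p = 0.277 and 0.125). At 15 mg/kg it also failed without cisplatin replicate 2 (-0.59, adjusted p = 0.149) or 10 (0.0577) or dose-group replicate 1 (0.0663), 3 (0.0629), 5 (0.0607) or 7 (0.0588). Map3k1, for an upstream kinase, fell by 1.83 (SE 0.29) and 1.31 (SE 0.29), the second not passing with library totals alone (-0.88, adjusted p = 0.118). Mapk12, for p38γ, fell by 1.25 (SE 0.24) at 30 mg/kg and Tab2, for a kinase adaptor, by 1.17 (SE 0.24) at 15 mg/kg, and neither passed with library totals alone (adjusted p = 0.107 and 0.146). Map2k3 was at -0.86 ± 0.32 (adjusted p = 0.0386) and -0.83 ± 0.32 (adjusted p = 0.0555). At 15 mg/kg its call ended in 11 of 22 alternatives, with -0.25 without cisplatin replicate 10, and at 30 mg/kg it was gained in 8 of 22.

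Immediate early genes fell in 12 of 22 cases at 15 mg/kg and 6 of 22 at 30 mg/kg, and none rose (14 and 8 adjusted over the list alone). Camera adjusted p was 0.000317 and 0.00387, and with an estimated correlation adjusted p was 0.672 and 0.76. Without cisplatin replicates 9 and 10 the call at 30 mg/kg ended (adjusted p = 0.243). Nr4a1 fell by 2.87 (SE 0.52) and 2.32 (SE 0.51), and without these libraries was at -1.43 (adjusted p = 0.0119) and -0.95 (adjusted p = 0.0998). Of 28 pro-apoptotic genes 8 rose and 5 fell at 15 mg/kg and 7 rose and 2 fell at 30 mg/kg (9 and 6, and 7 and 2, adjusted over the list alone), with no call of the list (camera adjusted p = 0.652 and 0.672). Dffb, for a nuclease that cuts DNA in apoptosis, fell by 1.38 (SE 0.25) and 1.31 (SE 0.24), though not with library totals alone (adjusted p = 0.0794 and 0.145). Bax (-0.08 ± 0.24, adjusted p = 0.809, and -0.45 ± 0.24, adjusted p = 0.159) was not called, but it was lower at 15 mg/kg after adjustment for GC content and exon length (-0.62, adjusted p = 0.0134). Of the survival genes, Dad1 rose by 1.35 ± 0.24 and 1.00 ± 0.23, while Birc2 fell by 1.44 (SE 0.27) and 0.95 (SE 0.26), the latter not with library totals alone (adjusted p = 0.253). Bcl2 was at -0.68 ± 0.24 (adjusted p = 0.0307) and -0.58 ± 0.24 (adjusted p = 0.0717), and its call at 15 mg/kg ended in 12 of 22 alternatives, among them without cisplatin replicate 6 (adjusted p = 0.0604), 9 (0.0728) or 10 (0.0511) and without dose-group replicate 2 (0.0856) or 5 (0.0954).

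**Figure D3:**
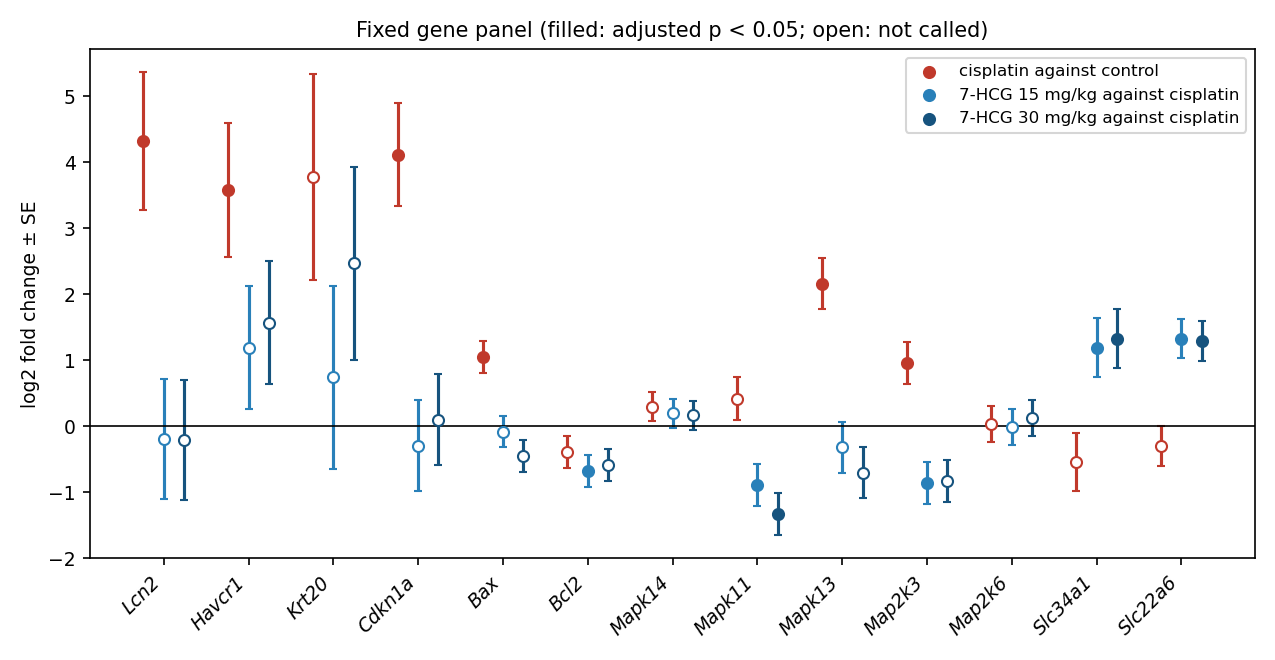
Of the 14 genes fixed as a panel, 13 in 3 comparisons. The x axis lists the genes, the y axis gives the log2 fold change, and error bars are the standard error of the edgeR fit (5 animals per group). Filled points passed at an adjusted p below 0.05 and open points did not. Lcn2, Havcr1 and Cdkn1a lie above 3 after cisplatin and are not called between 7-HCG and cisplatin.

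Altogether 2811 genes were higher and 2767 lower at 15 mg/kg than in cisplatin, and 2180 were higher and 1968 lower at 30 mg/kg. Past a 2-fold change there were 1198 up and 1730 down at 15 mg/kg and 741 up and 1319 down at 30 mg/kg. The authors' deposited table marks, at the same size, 1285 up and 1696 down and 822 up and 1413 down. Under library totals alone the counts were 1537 up and 509 down and 1220 up and 193 down, where the median of all genes stood 0.23 and 0.39 above 0. Lower calls outnumbered higher ones at 30 mg/kg with DESeq2 size factors (1796 up, 2329 down), with DESeq2 (2030 and 2849) and with mitochondrial mRNAs left out (1965 and 2176). They also did after adjustment for GC content and exon length (2032 and 2168), but not with limma voom (2628 and 2293). Without cisplatin replicates 9 and 10, 3886 and 2222 genes were called. The test recovered 27% and 35% of genes changed 2-fold, and 79% and 75% of those changed 4-fold, in simulated data for these comparisons. The doses shared 3478 calls in the same direction and none in the opposite one. Independent lists would share 412.4 up and 366.5 down, and simulated doses without effect shared 0. The simulations are not matched to the data, since with the cisplatin effect kept they called 2936.7 genes for cisplatin on average, against 1994. With the cisplatin libraries split so that the doses shared none, the overlap ranged from 46 to 1819 (median 1174 over 20 values). Camera called 88 of the 270 KEGG pathways at 15 mg/kg (66 higher, 22 lower) and 80 at 30 mg/kg (61 higher, 19 lower), and none with an estimated correlation. At 15 mg/kg the smallest camera adjusted p were those of Ribosome (104 of 148 genes rose and 2 fell, 1.49e-16) and Proteasome (26 of 43 rose and 0 fell, 3.05e-09). At 30 mg/kg it was that of Peroxisome (40 of 80 rose and 0 fell, 4.02e-09). First among the lower ones were MicroRNAs in cancer at 15 mg/kg (42 of 132 fell and 6 rose, 0.000236) and ECM-receptor interaction at 30 mg/kg (23 of 77 fell and 2 rose, 0.000744). The mean of both doses differed from cisplatin in 6079 genes, 2985 up and 3094 down.

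Between the 2 doses edgeR called no gene, with 1066 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.677. DESeq2 called 1 gene, the globin gene Hbb-bs (-6.93, adjusted p = 0.0177), named here after its value was seen, which has a near-identical copy. Hbb-bs stood at 7.41 ± 16.1 CPM at 15 mg/kg and 0.0637 ± 0.0763 CPM at 30 mg/kg, near the level of 3 counts. The red blood cell list mean was 2.2 in replicate 3 at 15 mg/kg and -1.847 to -1.266 in all other 7-HCG libraries, so this call may rest on 1 library. In simulated data the comparison of the doses recovered 32% of genes changed 2-fold and 84% of those changed 4-fold. The injury means differed by 0.31 (exact permutation test, p = 0.683) and the transporter means by 0.05 (exact permutation test, p = 0.802). Camera called 27 of the 270 KEGG pathways between the doses (7 higher and 20 lower at 30 mg/kg), and 0 with an estimated correlation. Ribosome had the smallest adjusted p and was lower at 30 mg/kg (median log2 difference -0.41, camera adjusted p = 2.31e-18).

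The comparisons of 7-HCG with control asked how far the treated kidneys stood from untreated ones. Here 45.2% of all tested genes were called at 15 mg/kg (3411 up, 3298 down) and 34.2% at 30 mg/kg (2771 up, 2317 down), the shares to set beside counts of list members. As lists, injury and p53 genes were higher than in control at both doses, though not in every animal. Replicate 3 at 15 mg/kg had a p53 mean of 3.065, below all controls (3.313 to 3.65), and an injury mean of 2.985, within the controls. These list means per animal were not tested against control. Of 29 injury markers 17 rose at each dose and 2 and 1 fell, with the same counts adjusted over the list alone. Of 32 p53 targets 16 rose and 1 fell at 15 mg/kg and 20 rose and none fell at 30 mg/kg (16 and 1, and 22 and 0, adjusted over the list alone). Lcn2 was higher by 4.13 ± 1.03 and 4.11 ± 1.03, Havcr1 by 4.77 ± 1.08 and 5.15 ± 1.10 and Cdkn1a by 3.82 ± 0.77 and 4.21 ± 0.78. By camera, adjusted p was 0.0106 and 0.00078 for injury and 0.00799 and 7.18e-06 for p53, and with an estimated correlation adjusted p was 0.663 and 0.538, and 0.663 and 0.394. The p38 list was not called (7 rose and 6 fell, and 5 rose and 5 fell, with 7 and 5, and 5 and 5, adjusted over the list alone, camera adjusted p = 0.874 and 0.833).

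Metabolic genes were higher than in control too. Of 36 fatty acid oxidation genes 32 and 30 rose and none fell (33 and 32 adjusted over the list alone), with Acadvl at 2.24 ± 0.26 and 2.40 ± 0.27 and Hadha at 1.81 ± 0.20 and 1.55 ± 0.20. Of 33 oxidative phosphorylation genes 25 and 16 rose and none fell (28 and 17 adjusted over the list alone), with Sdhd at 1.40 ± 0.20 and 1.42 ± 0.20. Of 39 transporters 15 rose at each dose and none fell (15 and 16 adjusted over the list alone), and of 29 NRF2 targets 20 and 19 rose and 2 and 0 fell (22 and 2, and 19 and 1, adjusted over the list alone), with Gsta3 at 2.94 ± 0.34 and 2.68 ± 0.33. Camera adjusted p was 1.08e-11 and 9.2e-15 for fatty acid oxidation, 5.96e-09 and 1.51e-06 for oxidative phosphorylation, 0.000133 and 1.66e-05 for transporters and 1.35e-05 and 2.39e-06 for NRF2. With an estimated correlation adjusted p at the 2 doses was 0.436 and 0.328, 0.436 and 0.394, 0.587 and 0.474, and 0.436 and 0.328, in that order.

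Matrix, endothelial and cell cycle genes were lower than in control. Of 30 matrix genes 24 and 22 fell and none rose (24 at each dose adjusted over the list alone). Of 12 endothelial markers 8 and 10 fell and none rose (11 and 10 adjusted over the list alone), with the receptor gene Tek at -2.08 ± 0.45 and -2.14 ± 0.45. Of 34 cell cycle genes 14 and 16 fell and 2 and 1 rose (14 and 2, and 17 and 2, adjusted over the list alone), with Mki67 at -2.40 ± 0.50 and -3.22 ± 0.52. Mitochondrially encoded mRNAs fell in 13 and 12 of 13 cases (13 at each dose adjusted over the list alone), with mt-Nd5 at -3.24 ± 0.59 and -2.94 ± 0.58. By camera, adjusted p was 6.69e-07 and 3.53e-08 for matrix, 0.000716 and 8.26e-06 for endothelium, 0.00155 and 4.37e-05 for cell cycle and 1.35e-05 and 1.42e-06 for mitochondrial mRNAs. With an estimated correlation adjusted p was 0.448 for endothelium and 0.436 for the other 3 lists at 15 mg/kg, and 0.328 for all 4 at 30 mg/kg. In total 6709 genes differed from control at 15 mg/kg (3411 up, 3298 down) and 5088 at 30 mg/kg (2771 up, 2317 down). Without control replicates 2 and 5 the counts were 4216 and 2748. This fit kept replicate 5 at 15 mg/kg and replicate 6 at 30 mg/kg, where adipose markers were also high. Under library totals alone the counts were 3102 and 2051. At 30 mg/kg library totals gave 926 up and 1125 down, so that the larger side was the lower one. Past a 2-fold change there were 1579 up and 2206 down, and 1071 up and 1755 down. In the authors' deposited table there were 1694 up and 2772 down, and 1064 up and 2628 down, at the same size.

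To ask whether 7-HCG moved cisplatin-changed genes back toward control, the 1994 genes called for cisplatin were followed. At 15 mg/kg 71.9% and at 30 mg/kg 73.2% had the opposite sign in the comparison with cisplatin. Of these genes 609 and 570 were called in the opposite direction, and 74 and 53 in the same direction. Genes that rose after cisplatin and fell under 7-HCG numbered 473 and 453, against 232.8 and 165.6 for independent lists. Genes that fell after cisplatin and rose under 7-HCG numbered 136 and 117, against 140.8 and 109.2. Both comparisons use the same 5 cisplatin libraries, which alone gives opposite signs. In simulations that kept the cisplatin effect and gave 7-HCG none, 65% and 65.2% of called genes had the opposite sign and 0 and 0.1 genes on average were called in the opposite direction. These simulations called 2936.7 genes for cisplatin on average, against 1994 in the data, so they are not a matched baseline. The covariance of the log2 fold changes across all genes was -0.295 and -0.286, against -0.100 and -0.103 in these simulations. Their correlation across genes, which are not independent replicates, was -0.331 and -0.347, against -0.229 and -0.235 in these simulations. In simulations where no group differed the correlation was -0.528 and -0.533 and the covariance -0.093 and -0.094. With the cisplatin libraries split between the comparisons, the opposite-sign share ranged from 35.4% to 82.3% (median 60%) and from 37.5% to 83.1% (median 60.4%). The covariance over these splits ranged from -0.341 to 0.017 (median -0.1505) and from -0.329 to 0.017 (median -0.131). The share was 63.4% and 64.4% without cisplatin replicates 9 and 10. Of the genes called between 7-HCG and cisplatin, 87.8% at 15 mg/kg and 85% at 30 mg/kg were not called after cisplatin itself, which called 13.4% of all tested genes.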

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

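The tests of the mitochondrial mRNA share, of the number of genes called, of the p38 list and of other splits of the libraries were all chosen after these results had been seen, and the list tests were planned.

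Of 24 groups of 5 list means, mitochondrial shares or library totals, tested at both ends, 1 library stood apart: replicate 2 at 15 mg/kg had a transporter mean of 7.14, against 7.69 for its nearest neighbour and 7.86 at the other end. Chance gives such a library in about 1 of 20 groups.

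Camera called 7 lists between 30 and 15 mg/kg although edgeR called no gene there. Higher at 30 mg/kg were p53 targets (median log2 difference 0.35, adjusted p = 0.00123) and immediate early genes (0.45, adjusted p = 0.0447). Lower were interferon-stimulated genes (-0.41, adjusted p = 5.21e-05), oxidative phosphorylation (-0.31, adjusted p = 0.000131), thick ascending limb markers (-0.25, adjusted p = 0.00291), macrophage markers (-0.48, adjusted p = 8.19e-05) and T and NK cell markers (-0.87, adjusted p = 0.0447). Each had adjusted p = 0.975 with an estimated correlation. The p53 call ended without replicate 1 (adjusted p = 0.0504) or 3 (0.421) at 15 mg/kg or 6 (0.0887) at 30 mg/kg. The immediate early call ended without replicate 1 (0.301) or 3 (0.676) at 15 mg/kg or 5 (0.0655) or 6 (0.277) at 30 mg/kg and with the CPM filter (0.0772), and that of T and NK cells in 13 of 19 alternatives.

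The mitochondrial mRNA share was lower in all 7-HCG libraries than in any other library. Depth argues little for it: the slope within groups and a 1.38-fold difference in depth would give a change of -1.7 percentage points (95% interval -10.26 to 6.85), against -31.8 observed. After adjustment for GC content and exon length, 13 of 13 mitochondrial mRNAs were still called for the mean of both doses (median log2 change -4.23, from -4.06). The adjustment removes a trend fitted over all genes, on which these 13 weigh little. It shows only that a trend shared by all genes does not give this difference. A handling or library batch shared by the 7-HCG animals cannot be told apart from 7-HCG itself, since 0 control or cisplatin libraries reach the 7-HCG range and the labels name no batch. An effect of 7-HCG on these mRNAs stays open as well, and no group received 7-HCG alone.

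A total of 6079 genes was called for the mean of both 7-HCG doses against cisplatin. With mitochondrial mRNAs left out before scaling, 6135 genes were called (5927 shared), and after adjustment for GC content and exon length 5847 were (4810 shared). GC content and exon length do not account for the count as a whole. TMM scaling already offsets the share of the mitochondrial mRNAs, with factors of 0.382 and 0.429 for cisplatin replicates 9 and 10. Leaving these mRNAs out could therefore change the count only little. It does not weigh what else a different mitochondrial share may reflect. Of the genes called at 15 and 30 mg/kg against cisplatin, 66.2% and 54.3% (3693 and 2252) were also called in the same direction against control. Both comparisons of a dose use the same 7-HCG libraries. With these split between them, 770 to 2252 genes (median 1719) were shared at 15 mg/kg and 34 to 902 (median 707) at 30 mg/kg. A batch shared by the 7-HCG libraries and an effect of 7-HCG would each give such sharing and cannot be told apart, since the labels name no batch.

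The p38 list was lower under 7-HCG than under cisplatin. Its median log2 change at 15 mg/kg without cisplatin replicates 9 and 10 went from -0.51 (quartiles -0.87 to 0) to -0.1 (-0.73 to 0.21, adjusted p = 0.156), which keeps 20.6% of its size, so these 2 libraries may account for most of it. At 30 mg/kg it went from -0.42 (quartiles -0.86 to 0.01) to -0.26 (-0.65 to 0.06, adjusted p = 0.13), which leaves the part of these libraries open. With mitochondrial mRNAs left out before scaling, the larger camera adjusted p of the doses was 0.00728. TMM scaling already offsets their share, so this could hardly differ and does not weigh these mRNAs as a cause. An effect of 7-HCG stays open at both doses.

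Other splits of the same libraries, 100 per comparison with the real one included, tested how often a split calls as many genes. The real split was the only 1 of 100 to do so for cisplatin with control (1994 genes, highest other split 720), 15 mg/kg with cisplatin (5578, highest 3026), 30 mg/kg with cisplatin (4148, highest 340), the mean of both doses with cisplatin (6079, highest 2927), 15 mg/kg with control (6709, highest 3192) and 30 mg/kg with control (5088, highest 366). This makes chance less likely but does not exclude it, since 100 splits cannot show less than 1 in 100. For the mean of both doses 3003 splits were possible. Between the doses the real split called 0 genes, so that each of the 100 splits calls as many and their number says nothing. The highest other split there called 243, which may reflect a structure of the animals other than dose. This was not tested.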

How the results depend on the processing

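The fits without cisplatin replicates 9 and 10, without mitochondrial mRNAs, without control replicates 2 and 5 and with an adjustment for GC content and exon length, the low-count filters in the list tests and the alternatives of the pathway counts were chosen after the data were seen. Across 134 named gene values and 3069 comparisons with an alternative, 2872 kept direction and side of the threshold, 157 lost a call, 20 gained one and 20 changed sign, with the replicate block included. Across 86 named list tests and 1880 comparisons, 1707 kept both, 157 lost a call, 5 gained one and 11 changed sign. Of the lost list calls, 77 were with an estimated correlation, 21 with 1 library left out and 19 with fry, and library totals ended none. Leaving out 1 library ended 39 gene calls, library totals 15, and the fit without cisplatin replicates 9 and 10 ended 9. None of the values that changed sign was called in the first place. The cause was not tested, unless fewer libraries or a smaller set of genes are named. Shallow libraries limit genes at low counts. The 2-fold changes recovered on simulated data were 27% to 35% in the 4 comparisons simulated. Except between the doses, far fewer genes were changed there than were called in the data, so these rates do not carry over to the other comparisons. Fits without mitochondrial mRNAs gave no value for those genes and their list, the CPM filter none for T and NK cells, and the fit of only the compared groups none for Saa3 after cisplatin.

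With library totals as the only scaling, the genes called were 883 for cisplatin with control, 2046 and 1413 for 15 and 30 mg/kg with cisplatin, 3026 for the mean of both doses and 3102 and 2051 for the doses with control. The share of higher calls moved with it: 207 up and 676 down, 1537 up and 509 down, 1220 up and 193 down, 2283 up and 743 down, and 1216 up and 1886 down for 15 mg/kg with control, with the median of all genes at -0.35, 0.23, 0.39, 0.31 and -0.14. For 30 mg/kg the split was 2030 up and 2849 down with DESeq2 against cisplatin, 2416 up and 3334 down with DESeq2 against control and 2194 up and 2783 down with DESeq2 size factors against control. Under library totals the injury difference after cisplatin was 1.56 (exact permutation test, adjusted p = 0.198), that of 30 mg/kg with cisplatin 0.40 and that of the mean of both doses 0.18, and 11 lists were called between the doses. DESeq2 size factors turned the transporter difference between the doses to -0.01, and DESeq2 called 1 gene there. A fit of the compared groups only called 1193 genes for cisplatin with control.

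Without cisplatin replicates 9 and 10 (fewer libraries), 691 genes were called for cisplatin with control, 2222 for 30 mg/kg and 3919 for the mean of both doses with cisplatin. With mitochondrial mRNAs also left out the counts were 713, 2188 and 3878. With only the 2 libraries left out, the injury difference after cisplatin was 2.11 with the groups still separate (exact permutation test, adjusted p = 0.0893), and 3 against 5 animals cannot give a smaller p. In that fit the opposite-sign shares were 63.4% and 64.4%, 9 lists were called at 15 mg/kg, and 30 pathways after cisplatin. Leaving out mitochondrial mRNAs too gave 8 lists at 15 mg/kg, 7 at 30 mg/kg and 29 pathways. Without control replicates 2 and 5, 292 genes and 16 pathways were called after cisplatin, and 4216 and 2748 genes for the doses with control. The adjustment for GC content and exon length called 20 pathways after cisplatin. An estimated correlation left 0 lists in all 6 comparisons reported and 0 pathways in cisplatin with control and each dose with cisplatin, and fry left 0 lists between the doses. The opposite-sign share was 57.3% and 60.3% over all tested genes, 74% at 15 mg/kg over genes past 2-fold, and 35.4% to 82.3% (median 60%) and 37.5% to 83.1% (median 60.4%) over splits of the cisplatin libraries.

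Leaving out 1 library at a time gave 829 to 2179 genes for cisplatin with control and 0 to 2 between the doses. Opposite-sign shares were 66% to 80.7% at 15 mg/kg and 68.8% to 82.1% at 30 mg/kg. Injury differences were 1.97 to 2.32 after cisplatin, -0.72 to 0.04 at 15 mg/kg, -0.53 to 0.31 at 30 mg/kg and -0.19 to 0.78 between the doses, where transporter differences were -0.09 to 0.15. Lists called were 10 to 18 at 15 mg/kg and 5 to 11 between the doses, and pathways after cisplatin 1 to 25.

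Changes of sign in values that were not called were as follows. After cisplatin, Mapk14 was -0.19 under library totals, -0.03 without cisplatin replicates 9 and 10, with or without mitochondrial mRNAs, and -0.05 without replicate 10, and Slc22a6 was 0.01 without control replicate 7. Leaving out 1 library gave -0.05 to 0.40 for Mapk14 and -0.50 to 0.01 for Slc22a6. The adipose list turned higher without control replicates 2 and 5 (camera adjusted p = 0.496). At 15 mg/kg against cisplatin, library totals gave Bax 0.10 and Cdkn1a 0.01. Without dose-group replicate 1 Bax was 0.04 and Lcn2 0.10, and without replicate 3 Bax was 0.07, Lcn2 0.13 and Cdkn1a 0.02, while Cdkn1a was 0.03 without cisplatin replicates 9 and 10. Leaving out 1 library gave -0.27 to 0.07 for Bax, -0.63 to 0.13 for Lcn2 and -1.06 to 0.02 for Cdkn1a. The pro-apoptotic list turned lower after adjustment for GC content and exon length (signed adjusted p = -0.856). At 30 mg/kg against cisplatin, library totals gave Lcn2 0.09. Without dose-group replicate 1 Lcn2 was 0.10 and the injury and p53 lists turned higher (camera adjusted p = 0.705 and 0.95). Cdkn1a was -0.02 with DESeq2 size factors and with DESeq2, -0.01 after adjustment for GC content and exon length and -0.45 without replicate 6. Leaving out 1 library gave -0.98 to 0.10 for Lcn2, -0.45 to 0.37 for Cdkn1a, and signed adjusted p of -0.716 to 0.705 for the injury list and -0.644 to 0.95 for p53. The p38 list against control, with its adjusted p signed by direction, was at -0.881 and -0.983 with the CPM filter at 15 and 30 mg/kg, and at 15 mg/kg at -0.921 after adjustment for GC content and exon length, -0.936 without control replicate 7 and -0.98 without dose-group replicate 2 (range -0.98 to 0.948 leaving out 1 library).

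A fit with the replicate number as a block (replicate block) was run although the numbers do not pair the animals: of 15 pairs sharing a number 3 had a correlation above 0.1 (range -0.309 to 0.234), 0 of 18 libraries correlated best with their own number, and numbers 9 and 10 each occur in 1 library. Of the 157 gene calls and 157 list calls lost in all, 63 and 11 were lost in this fit. The replicate block called 17 genes for cisplatin with control, 1329, 310 and 1343 for 15 mg/kg, 30 mg/kg and the mean of both doses with cisplatin, 10 lists at 15 mg/kg and 20 pathways after cisplatin. Its opposite-sign share was 82.4% at each dose. In it, Cdkn1a was -0.18 at 30 mg/kg, the transporter list after cisplatin turned higher (camera adjusted p = 0.532) and so did the injury list at 30 mg/kg (0.818).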

Other observations

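The relation of the inflammatory list to the injury list and the thinning of libraries were tested on a pattern already seen, and the list tests were planned.

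Straight-segment (S3) markers of the proximal tubule were higher under 7-HCG than under cisplatin. Of 10 markers 6 rose and none fell at each dose under both adjustments (camera adjusted p = 0.0192 and 0.00711, and adjusted p = 0.703 and 0.72 with an estimated correlation). Both calls ended without cisplatin replicates 9 and 10 (camera adjusted p = 0.207 and 0.13), and that at 15 mg/kg also without replicate 10 alone (0.0568). Against control, of 28 pro-apoptotic genes 12 rose and 1 fell at 15 mg/kg and 13 rose and 1 fell at 30 mg/kg (12 and 1, and 14 and 1, adjusted over the list alone), with camera adjusted p = 0.0118 and 0.00471, and adjusted p = 0.436 and 0.328 with an estimated correlation. The call at 15 mg/kg ended after adjustment for GC content and exon length (0.0809). Of 14 glucocorticoid-responsive genes 8 rose and none fell at each dose under both adjustments (camera adjusted p = 0.015 and 0.000766, and adjusted p = 0.587 and 0.328 with an estimated correlation).

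T and NK cell and red blood cell mRNAs were lower than in control in all groups given cisplatin. Against control, T and NK cell markers fell in 8 and 10 of 10 cases under both adjustments (camera adjusted p = 0.00392 and 1.85e-05, and adjusted p = 0.436 and 0.328 with an estimated correlation). Of 7 red blood cell markers 6 fell at each dose (7 and 6 adjusted over the list alone, camera adjusted p = 4.71e-05 and 1.42e-06, and adjusted p = 0.436 and 0.215 with an estimated correlation).

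Among the 10 animals given 7-HCG, injury markers, p53 targets and immediate early genes varied together. A hypothesis is that the animals differed in the extent of injury, in which case inflammatory genes should vary with injury too. The inflammatory list (30 genes, none shared with the injury list) rose with the injury list (Pearson r = 0.859, permutation p = 0.00109, adjusted p = 0.00145 over 4 relations, Spearman rho = 0.806, permutation p = 0.00725). Without the 2 animals farthest from the median r was 0.566 (exact permutation test over 8 animals, p = 0.142, adjusted p = 0.177), so it passed only with these animals, whose removal also narrows the range of injury. Around the means of the 2 doses r was 0.86 (exact permutation test within doses, p = 0.00396, adjusted p = 0.00528). Depth was tested as the alternative: thinning each library to 25972128 counts kept 99.3% of the range of the injury means (3.83 of 3.86). The deepest of these libraries held 49602115 counts, so thinning could move means of scaled counts only little. It shows only that the number of counts does not make this range. Lists of other genes moved the same way between the animals with the lowest and highest injury means, replicate 3 at 15 mg/kg and replicate 6 at 30 mg/kg. The fatty acid oxidation mean was 6.852 and 8.066 there, and the NRF2 mean 6.568 and 8.072. The mean of the adipose list differed between them as well, with 0.658 and 4.413. The inflammatory list therefore cannot tell the extent of injury from other differences between the animals. The hypothesis may hold for these animals, but it was found and tested on the same libraries, and no measure of kidney function was analysed here.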
